A study of Homo sapiens with 4 samples.

How the data were processed

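Gene expression was measured on 4 microarrays of cultured human innate lymphoid cells of group ILC3 from tonsil. Per the labels, the cells had been sorted by surface markers as CD56+ NKp44+ CD196+ CD300LF+ CD103-, and were then expanded for 15 to 20 days in interleukin-7 and stem cell factor, each at 10 ng/ml. There were 2 arrays of cultures left without further stimulation and 2 of cultures stimulated overnight with interleukin-23, interleukin-15 and interleukin-1b, each at 50 ng/ml. The groups and the numbers of the arrays were taken from the sample titles. The labels name a pair of RNA amplification kits, Ovation Pico SL and Ovation Pico, without saying which array used which, so a kit effect could not be tested. They do not say whether the arrays of a group came from separate donors or cultures, and p-values therefore measure the spread between these samples, which may be technical. The labels give no date or slide.

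The deposited values are intensity values of probe sets that the authors made with RMA, per the submitters' processing notes (the version is not stated). RMA corrects background, normalizes between arrays by quantiles and summarises the probes of a probe set. RMA usually ends on a log2 scale, whereas these values had a lowest intensity of 2.42 and medians per array between 41.7 and 44.6, so they were read as linear. The array design, the annotation release and any filter on probe sets by the submitters are not given in the sources used here. Of 2 deposited tables, the series table was used, and 0 values differed between it and the other. The tables hold no detection calls and no probe-level signals, so the background correction was not repeated, and the number of arrays limits the precision.

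Probe sets were named from the description column of the other deposited table. Of 21462 probe sets, 19170 named 1 gene and 2292 named several. Current symbols were taken from a table of human RefSeq genes (assembly GRCh38.p14) through the Entrez identifier for 18868 of the 19170, which updated 2544 symbols, and 302 kept the deposited name. This gave 18433 genes, of which 599 had several probe sets. The probe set with the highest mean over the 4 arrays stood for its gene. Probe sets naming several genes were left out, except 1 that was kept in the tests and in the counts of genes, was counted in no gene list and is not reported here.

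Values were transformed to log2(intensity + 1), and every fold change is on that scale, which understates the change of dim genes. Genes whose mean fell below the 30th percentile of the probe set means, a log2 value of 4.54, were left out of the tests, which left 12864. XIST, TSIX and Y-linked genes were left out throughout. Stimulated and unstimulated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 prior variance for all genes, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. "Rose" and "fell" are used of genes past that threshold. No replicate block was used, because the labels do not say that a number marks a donor. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so single genes were tested only through limma, which pools information on the spread across genes. The prior carried 4.66 degrees of freedom, for 6.66 in all.

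Before the data were examined, 36 gene lists were fixed, covering effector functions, identity, signalling responses, metabolism, growth, stress and markers of other cell types. The 33 with at least 4 measured members were tested with camera from limma, with a preset correlation between genes of 0.01 and adjustment over the 33 lists. Beside each count of members past the threshold over all genes stands the count adjusted over the list alone. Camera was also run with the correlation estimated for each list, and fry was run on the same lists. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Some genes, such as GZMB, BATF and IL2RA, belong to several lists.

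The rule for naming genes was also fixed before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose stimulated values both lay on the same side of both unstimulated values. It added a fixed set of cytokine, receptor, transcription factor and sort marker genes, whatever their values. From each fixed list it added up to 4 members past the threshold with the largest change, or the 2 largest changes where none passed. Immunoglobulin and T cell receptor segments were not named under the first part. Genes named outside this rule are given as chosen after their values were seen.

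The tests were first tested on simulated data made from the means and spread of these arrays, with 200 genes changed per run over 10 runs of 12864 genes. At a log2 change of 1 limma recovered 18.2% of the changed genes, at 2 it recovered 92.4% and at 3 it recovered 99.2%, with 5.87% false calls among all calls. A changed list, with 10 members raised by 2 on the log2 scale, passed camera in 10 of 10 runs and an unchanged list in 0 of 10. Lists with smaller changes were not simulated. The simulated genes varied independently of each other, with variances drawn from limma's fitted prior. These rates therefore do not show how limma or camera behave where genes are correlated.

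Alternatives were no filter, a filter at the 50th percentile, the mean of a gene's probe sets, quantile normalization, centring each array on its median, a pseudocount of 16, an intensity trend in the prior variance, the replicate number as a block, the other deposited table, and leaving out each array in turn. Where an array was left out, the lone array of its group was assumed to vary like the other group. A call lost in an omission can therefore reflect the spread of the other group. Groups of 2 are too small for an outlier test or for a count over other splits of the samples, and neither was made. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.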

Results

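The arrays addressed how ILC3, innate lymphocytes that make interleukin-22 at mucosal surfaces, change their transcripts after overnight exposure to interleukin-23, interleukin-15 and interleukin-1b. There were 2 unstimulated and 2 stimulated arrays of cells expanded from tonsil in interleukin-7 and stem cell factor. Median intensities were 43.1 and 44.6 on the unstimulated arrays and 41.7 and 43.2 on the stimulated ones. Across probe sets, log2 values correlated at r = 0.977 between the unstimulated arrays, at 0.982 between the stimulated arrays and at 0.951 to 0.962 between groups. These correlations are across probe sets, which are not independent replicates.

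After stimulation, the transcripts of the ILC3 cytokine IL22 and of the type 1 cytokine IFNG rose from the low end of the intensity scale to far above the upper quartile of the arrays. IL22 went from a log2 intensity of 3.43 ± 0.12 to 12.39 ± 0.14 (SD, n = 2 each), a log2 fold change of 8.96 with a standard error of 0.18, or 498-fold (limma adjusted p = 1.19e-05). IFNG went from 3.21 ± 0.11 to 11.20 ± 0.68, a log2 fold change of 7.99 ± 0.31 (SE; adjusted p = 0.000225). CD274, which encodes the checkpoint ligand PD-L1, rose by 7.26 ± 0.28 from 3.55 ± 0.56 to 10.81 ± 0.08 (adjusted p = 0.000225). GZMB, the cytotoxic protease granzyme B, rose 37.5-fold from 5.63 ± 0.26 to 10.86 ± 0.16 (adjusted p = 0.000225). The unstimulated levels of IL22, IFNG and CD274 lay below the filter level of 4.54, so the size of these changes depends on the pseudocount. With a pseudocount of 16 the log2 fold changes were 7.71 for IL22, 6.61 for IFNG and 6.07 for CD274.

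Other genes among the 12 largest rises were SERPINA1, a protease inhibitor (log2 fold change 4.84), IFI30, a lysosomal thiol reductase (4.46), the chemokine gene CCL1 (4.45), malic enzyme ME1 (4.31), the tryptophanyl-tRNA synthetase WARS1 (4.28), CSF2, which encodes GM-CSF (4.19), and the fatty acid transporter SLC27A2 (4.12). SLAMF7, a receptor of activated lymphocytes, rose by 4.97 ± 0.69 (SE; adjusted p = 0.0127), but its call was lost without either stimulated array, with an adjusted p of up to 0.0723. The largest fall was in JAML, an adhesion molecule of the junctional family, which fell by 4.27 on the log2 scale, from 10.69 ± 0.27 to 6.42 ± 0.81 (SE 0.37, adjusted p = 0.00434). RNASE6 fell by 3.10, SPINK2, a protease inhibitor, by 3.07, and the chemokine gene XCL1 fell by 3.03. SCML4, PTGDR, which encodes a prostaglandin D2 receptor, SMIM14, AFF3, KIAA0087 and SRGAP3 fell by 2.81 to 2.38. TC2N fell by 3.12 (adjusted p = 0.0445) and MATN2, an extracellular matrix protein, fell by 2.71 (adjusted p = 0.0149). The call of TC2N was lost without unstimulated array 2 or stimulated array 1 (adjusted p up to 0.111), and that of MATN2 without stimulated array 2 (adjusted p = 0.0595). TC2N also missed the threshold with no filter (0.0670), quantile normalization (0.0600), centring (0.0577) and a pseudocount of 16 (0.0524).

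In all, 764 of 12864 genes passed the limma threshold, 515 higher and 249 lower after stimulation. Of these, 390 rose and 198 fell by at least 1 on the log2 scale, and 26 rose and 5 fell by at least 3. The smallest change that passed was 0.785. The values of the groups did not overlap for 6592 genes, or 51.2%, against 33.3% by chance with 2 arrays per group. Fewer genes passed with a stimulated array left out than with an unstimulated one. All 764 genes kept their direction each time, but a call needs a change larger than the gap between the arrays of a group. Leaving out 1 array therefore could not reverse a called gene. Among 94 named genes past the threshold, 44 passed with each of the 4 arrays left out.

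**Figure D1:**
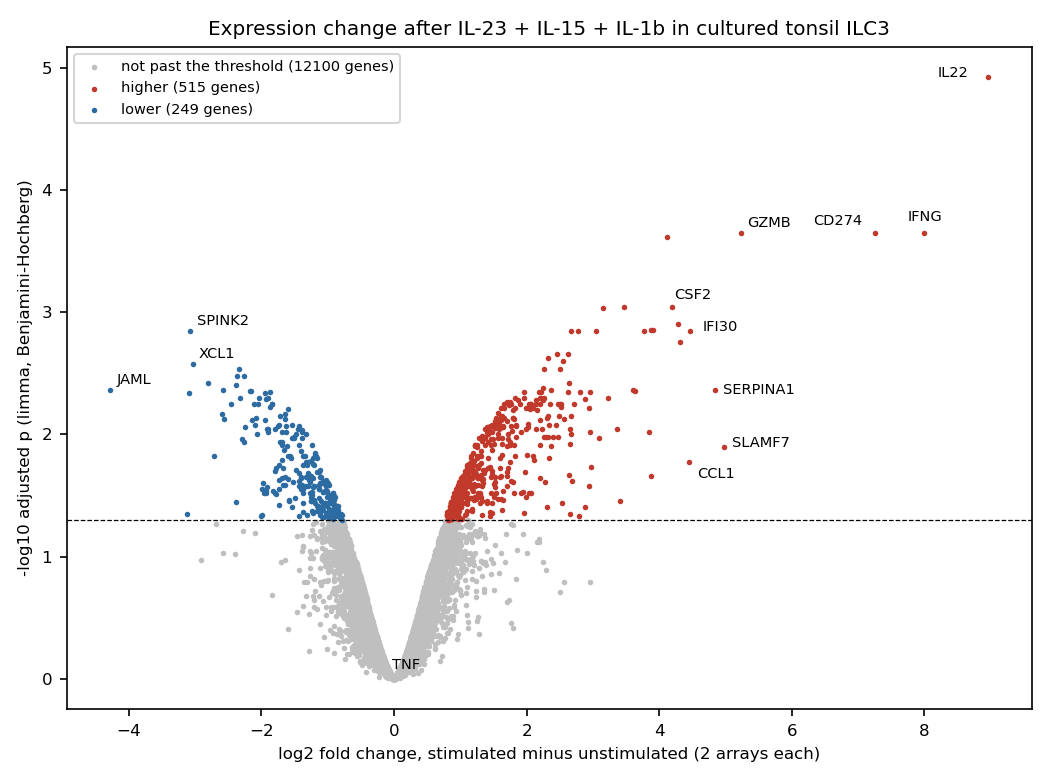
Log2 fold change (stimulated minus unstimulated, 2 arrays each) against -log10 of limma's adjusted p for each of 12864 genes. Red points are the 515 genes past the threshold and higher, blue points the 249 lower, grey points the rest, and the dashed line marks an adjusted p of 0.05; IL22 stands furthest to the right at 8.96 and JAML furthest to the left at -4.27.

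Cytokines and growth factors known from ILC3 were higher as a list. Of 14 measured members, 8 rose, 1 fell and 5 did not pass (adjusted over the list alone, 9 rose and 1 fell). CSF2 rose 18.3-fold (adjusted p = 0.000905) and TNFSF4, which encodes the costimulatory ligand OX40L, rose 8.91-fold (adjusted p = 0.000916). The cytokine gene IL17F rose by 1.86 ± 0.18 (SE; adjusted p = 0.00526), from 4.59 ± 0.15 to 6.46 ± 0.09. IL26 (2.94 ± 0.52), the neutrophil chemokine gene CXCL8 (3.41 ± 0.67) and LIF (1.64 ± 0.30) also rose, with adjusted p values of 0.0266, 0.0353 and 0.0292. IL26 and CXCL8 missed the threshold without either stimulated array (adjusted p up to 0.132 and 0.180), and LIF without unstimulated array 1 or stimulated array 2 (up to 0.098). CXCL8 also missed it with no filter (0.0535), quantile normalization (0.0613) and centring (0.0503), and LIF with quantile normalization (0.0505) and the mean of its probe sets (0.123). TNFSF13B, which encodes the B cell survival factor BAFF and was chosen after its values were seen, fell by 1.67. TNF was measured at 10.26 ± 1.01 and 10.13 ± 0.67, a log2 fold change of -0.13 ± 0.50 (adjusted p = 0.924; 95% interval -1.32 to 1.06), which was -0.84 and 0.58 without unstimulated arrays 1 and 2 and 0.34 and -0.60 without stimulated arrays 1 and 2. IL17A and IL2 lay below the filter and were not tested, with levels of 4.38 ± 0.14 and 4.34 ± 0.13 for IL17A and of 5.10 ± 0.74 and 3.21 ± 0.24 for IL2 without and with stimulation. The list's median log2 fold change was 1.68 (camera adjusted p = 4.02e-07; adjusted p = 0.306 with an estimated correlation).

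**Figure D2:**
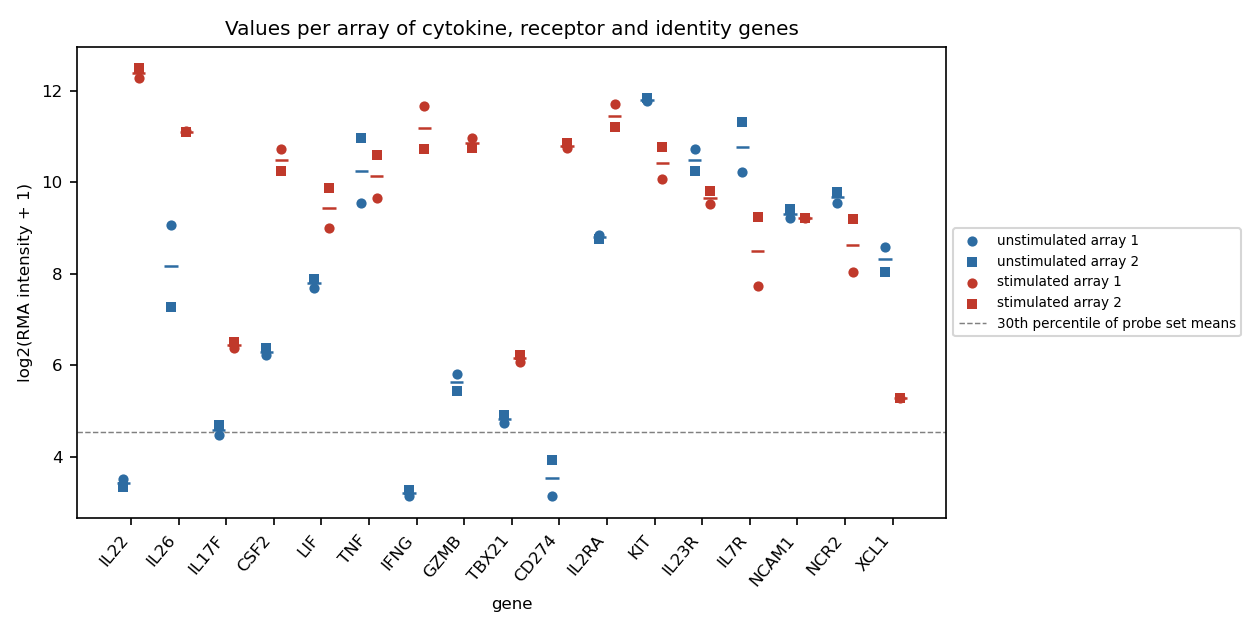
Log2(intensity + 1) of cytokine, receptor and identity genes on each of the 4 arrays, blue for unstimulated and red for stimulated, with circles for array 1, squares for array 2 and short lines at the group means. The dashed line is the filter level of 4.54; IL22 and IFNG lie below it without stimulation and at 12.39 and 11.20 on average after it, whereas the values of TNF overlap.

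Receptors and transcription factors that mark ILC3 were lower as a list after stimulation. Of 20 measured members, 3 fell, 1 rose and 16 did not pass (adjusted over the list alone, 11 fell and 2 rose). KIT, the receptor for stem cell factor, fell by 1.38 from 11.81 ± 0.05 to 10.43 ± 0.49 (adjusted p = 0.0303), PCDH9 fell by 1.73 and the Ikaros family gene IKZF2 fell by 0.97. The call of KIT was lost without either unstimulated array or stimulated array 1 (adjusted p up to 0.135), that of PCDH9 without either stimulated array (up to 0.186) and that of IKZF2 without any 1 of the 4 arrays (up to 0.198). PCDH9 also missed the threshold with no filter (0.0539), centring (0.0581) and a pseudocount of 16 (0.0544), and IKZF2 with centring (0.0511). The member that rose was BATF, an AP-1 family factor also counted among the STAT3 response genes. Log2 fold changes of other receptors and factors did not pass and were -2.28 ± 0.54 for IL7R (SE; adjusted p = 0.0621), -0.82 ± 0.22 for IL23R (0.0944), -0.67 ± 0.17 for IL1R1 (0.0720) and 0.16 ± 0.19 for AHR (0.724). The value of AHR ranged from 0.01 without stimulated array 2 to 0.30 without stimulated array 1, and it was 0.05 with quantile normalization. IL7R passed without unstimulated array 1 (-2.83, adjusted p = 0.0326) and without stimulated array 2 (-3.03, adjusted p = 0.0451). IL1R1 passed with quantile normalization (0.0437) and with a pseudocount of 16 (0.0438). The list's median was -0.70 (camera adjusted p = 0.000705; adjusted p = 0.314 with an estimated correlation).

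The genes of the surface markers used for the sort did not pass the threshold. NCAM1, which encodes CD56, changed by a log2 value of -0.09 ± 0.18 (SE; adjusted p = 0.833), NCR2, which encodes NKp44, by -1.05 ± 0.36 (0.157), CD300LF by 0.58 ± 0.20 (0.150) and ITGAE, which encodes CD103, by 0.41 ± 0.19 (0.297). CCR6, which encodes CD196, was at -0.24 ± 0.24 (0.639) by its brightest probe set and fell by 0.98 (adjusted p = 0.0272) when its probe sets were averaged. The value of NCR2 was -0.48 and -1.62 without stimulated arrays 1 and 2, that of ITGAE was 0.26 without stimulated array 2, and that of CCR6 ranged from -0.47 to -0.02 over the omissions of 1 array. NCAM1 was at -0.18 and 0.0021 without unstimulated arrays 1 and 2, and at -0.26 with quantile normalization.

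Type 1 and cytotoxic genes, which are typical of ILC1 and natural killer cells, moved both ways. Of 22 measured members, 4 rose, 2 fell and 16 did not pass (adjusted over the list alone, 5 rose and 2 fell). Beside IFNG and GZMB, the granule gene NKG7 rose by 2.06 (adjusted p = 0.0303) and TBX21, which encodes T-bet, rose by 1.32 ± 0.18 (SE; adjusted p = 0.0114), from 4.83 ± 0.12 to 6.15 ± 0.10. The lymphotactin genes XCL1 and XCL2 fell by 3.03 and 1.74. EOMES was at a log2 fold change of 0.65 ± 0.18 (adjusted p = 0.0895; log2 fold change 0.41 with a pseudocount of 16), and IKZF3 lay below the filter at 3.58 ± 0.11 and 4.25 ± 0.71. The list's median was 0.27 (camera adjusted p = 0.0230; adjusted p = 0.328 with an estimated correlation). The list missed the threshold without unstimulated array 1 (adjusted p = 0.109) and with the filter at the 50th percentile (0.126), and its median was 0.45 without stimulated array 2. TBX21 missed it without either stimulated array (up to 0.0869), NKG7 without unstimulated array 1 or stimulated array 2 (up to 0.0643) and XCL2 without stimulated array 1 (0.0708).

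Response genes of the pathways that the added cytokines are known to engage were higher. Of 29 measured NF-kB response genes, 17 rose, 0 fell and 12 did not pass (adjusted over the list alone, 23 rose). BCL2A1, an antiapoptotic BCL2 relative, rose by 3.47 (adjusted p = 0.000905), the adhesion molecule ICAM1 by 2.67 and the cytokine subunit EBI3 by 2.62, while PTGS2, the inducible cyclooxygenase, rose by 3.88 (adjusted p = 0.0217) but reached 0.0621 with a pseudocount of 16. Of 16 STAT3 response genes, 9 rose and 7 did not pass (adjusted over the list alone, 9 rose), with BATF at 3.22, the growth regulator MYC at 2.88 and the lymphocyte factor IRF4 at 2.37. Of 20 STAT5 response genes, 8 rose and 12 did not pass (adjusted over the list alone, 8 rose), among them IL2RA, the interleukin-2 receptor alpha chain, at 2.65 ± 0.22 (SE) and the kinase PIM2 at 2.19. Camera adjusted p values were 9.75e-18, 9.42e-08 and 3.88e-06 for medians of 1.32, 1.12 and 0.49 (adjusted p = 0.306, 0.314 and 0.328 with an estimated correlation). The STAT5 median was 0.81 without stimulated array 1.

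Of 19 AP-1 and immediate early genes, 2 rose, BATF3 by 3.60 and FOSL2 by 1.04, and 17 did not pass (adjusted over the list alone, 2 rose; camera adjusted p = 0.382). Among the 4 omissions FOSL2 passed only without unstimulated array 2 (otherwise adjusted p up to 0.201) and missed the threshold with quantile normalization (0.0592). The list itself passed without unstimulated array 2 (median 0.37, adjusted p = 0.00535) and had a median of -0.20 without unstimulated array 1. Of 23 cytokine receptors, 4 rose, 1 fell and 18 did not pass (adjusted over the list alone, 6 rose and 4 fell; camera adjusted p = 0.130). Those that rose were IL2RA, IL2RB at 2.11, IL15RA at 1.79 and CSF2RB at 1.62, and the 1 that fell was KIT. IL2RB and CSF2RB missed the threshold without either stimulated array (up to 0.0951 and 0.0639). Of 13 inhibitory receptors and feedback regulators, CD274 and SOCS3 rose (1.76 for SOCS3), CD200R1 fell by 1.92 and 10 did not pass (adjusted over the list alone, 3 rose and 1 fell; camera adjusted p = 0.119). This list passed without unstimulated array 2 (0.00587) and with no filter (0.0314). SOCS3 missed the threshold without stimulated array 2 (0.0591), and CD200R1 without either stimulated array (up to 0.140).

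Of 12 chemokine genes, CCL1 and CXCL8 rose, XCL1 and XCL2 fell and 8 did not pass (adjusted over the list alone, 5 rose and 2 fell; camera adjusted p = 0.182, and 0.0182 without stimulated array 2). Of 14 TNF receptor family and costimulation genes, TNFRSF1B rose by 1.07 and 13 did not pass (adjusted over the list alone, 1 rose; camera adjusted p = 0.125), and TNFRSF1B missed the threshold without any 1 of the 4 arrays (up to 0.229), with no filter (0.0582), with quantile normalization (0.0532) and with a pseudocount of 16 (0.0579). Of 18 homing and quiescence genes, the lymph node homing receptor CCR7 rose by 2.26 (adjusted p = 0.0105; 0.0558 without stimulated array 1) and 17 did not pass (adjusted over the list alone, 2 rose and 1 fell; camera adjusted p = 0.594, and 0.00869 without unstimulated array 2). The median of this list was 0.49 in that omission, -0.22 without unstimulated array 1 and -0.15 without stimulated array 2, against 0.02 with all arrays. Of 12 tissue residency and TGF-beta associated genes, 2 rose and 10 did not pass (adjusted over the list alone, 3 rose). PRDM1, which encodes the repressor BLIMP1, rose 14.7-fold (log2 fold change 3.88 ± 0.23, SE; adjusted p = 0.0014) and RGS1, a regulator of chemokine receptor signalling, rose by 2.20 (adjusted p = 0.0225; 0.0717 without stimulated array 1). That list's camera adjusted p was 0.00302 for a median of 0.40 (adjusted p = 0.314 with an estimated correlation). Of 18 regulators of apoptosis, 6 rose and 12 did not pass (adjusted over the list alone, 6 rose). The proapoptotic genes PMAIP1 (2.52) and BCL2L11 (2.28) were among them, as was the antiapoptotic BCL2A1. The median of this list was 0.18 (camera adjusted p = 0.0118; adjusted p = 0.328 with an estimated correlation), and it was 0.40 without unstimulated array 2.

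Interferon-stimulated genes were higher, and the guanylate-binding proteins were among the members with the largest changes. Of 23 measured members, 8 rose and 15 did not pass (adjusted over the list alone, 17 rose and 1 fell). GBP4 rose by 3.77 ± 0.24 (SE; adjusted p = 0.00143), GBP5 by 2.62 and the transcription factor IRF1 by 2.44, and IFIT3, an antiviral effector, rose by 2.35. The list's median was 1.35 (camera adjusted p = 1.22e-10; adjusted p = 0.383 with an estimated correlation), and it was 0.71 without stimulated array 2. Of 6 measured genes of MHC class II presentation, CTSS, a lysosomal protease, rose by 1.45, the invariant chain gene CD74 rose by 1.46, HLA-DMB fell by 0.87 and 3 did not pass (adjusted over the list alone, 2 rose and 1 fell; camera adjusted p = 0.365). CD74 missed the threshold without unstimulated array 1 or either stimulated array (up to 0.204), HLA-DMB without unstimulated array 2 or either stimulated array (up to 0.241) and CTSS without either stimulated array (up to 0.0643). CD74 and HLA-DMB also missed it with no filter (0.0651 and 0.0523), quantile normalization (0.0872 and 0.0555) and a pseudocount of 16 (0.0561 and 0.0702), and HLA-DMB with centring (0.0544). Beside these genes, VCAN and CD68, used as myeloid markers, rose by 3.85 and 1.57.

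Genes of growth and biosynthesis were higher as lists. Of 20 ribosome biogenesis factors, 11 rose and 9 did not pass (adjusted over the list alone, 18 rose), led by NOP16 at 2.33 ± 0.17 (SE; adjusted p = 0.00239). WDR12 at 1.53, NOLC1 at 1.41 and GNL3 at 1.34 missed the threshold without either stimulated array (adjusted p up to 0.148, 0.108 and 0.121). Of 17 genes of polyamine and nucleotide synthesis, 8 rose and 9 did not pass (adjusted over the list alone, 10 rose), among them the spermine synthase SMS at 2.04 and the purine synthesis enzyme PAICS at 1.56 (0.0708 without stimulated array 1). The medians of these lists were 0.95 and 0.87 (camera adjusted p = 2.49e-12 and 2.7e-06; adjusted p = 0.306 for both with an estimated correlation). By contrast, 0 of 21 cytosolic ribosomal protein genes passed by limma, 1 of them had an unadjusted p under 0.05, and their median was 0.13 (adjusted over the list alone, 0 passed; camera adjusted p = 0.202, and 0.0387 without unstimulated array 2). That median was 0.0017 without unstimulated array 1 and 0.22 without stimulated array 1. The largest changes in that list were 0.61 ± 0.50 for RPL18 and 0.49 ± 0.37 for RPS19 (SE), neither past the threshold, although without unstimulated array 2 they were at 1.41 (adjusted p = 0.0469) and 1.08 (0.0489) and passed, and without unstimulated array 1 they were at -0.18 and -0.10.

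Metabolic lists were also higher. Of 19 glycolysis genes, 4 rose and 15 did not pass (adjusted over the list alone, 12 rose). The lactate transporter SLC16A1 rose by 1.67 and the phosphofructokinase PFKP by 1.34. ENO2 (1.57) and LDHA (0.80) also rose, but missed the threshold with quantile normalization (limma adjusted p = 0.0507 and 0.0796). ENO2 did not keep its call in every omission of 1 array, and LDHA kept it in none. Over these omissions the log2 fold change ranged from 1.11 to 2.03 for ENO2 and from 0.74 to 0.87 for LDHA. Of 16 genes of amino acid transport and one-carbon metabolism, 6 rose and 10 did not pass (adjusted over the list alone, 7 rose), among them the amino acid transporters SLC7A5 at 1.81 and SLC7A1 at 1.46. SLC16A1 and PFKP missed the threshold without either stimulated array (adjusted p up to 0.0541 and 0.0831), and SLC7A5 and SLC7A1 without stimulated array 2 (0.0564 and 0.0808). Of 20 nuclear genes of the respiratory chain, 2 rose and 18 did not pass (adjusted over the list alone, 8 rose), and of 17 genes of cholesterol synthesis and uptake 1 rose and 16 did not pass (adjusted over the list alone, 6 rose). Medians of these 4 lists were 0.80, 0.71, 0.45 and 0.35, with camera adjusted p values of 3.8e-07, 3e-05, 0.00131 and 0.00557 (adjusted p = 0.398 for each with an estimated correlation). Without stimulated array 2 the amino acid median was 0.34, and without unstimulated array 2 the respiratory chain and cholesterol medians were 0.29 and 0.17. The members that rose in the last 2 lists were ATP5MC1 (1.08), CYC1 (0.84) and FDPS (0.93). Of the 4 omissions, ATP5MC1 passed only without unstimulated array 1 (otherwise up to 0.159), FDPS only without unstimulated array 2 (up to 0.187) and CYC1 in none (up to 0.262). With quantile normalization CYC1 and FDPS were at 0.0604 and 0.0587, and CYC1 was at 0.0505 with no filter and 0.0572 with an intensity trend in the prior variance.

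Stress and proliferation lists had few members past the threshold, or 0. Of 12 heat shock genes, HSP90AB1 (1.19) and HSPD1 (0.81) rose and 10 did not pass (adjusted over the list alone, 4 rose; median 0.45, camera adjusted p = 0.00167, and adjusted p = 0.314 with an estimated correlation). HSP90AB1 missed the threshold without either stimulated array (up to 0.120), and HSPD1 without any 1 of the 4 arrays (up to 0.227) and with quantile normalization (0.0915). By limma, 0 of 19 genes of the endoplasmic reticulum stress response, 0 of 19 DNA replication genes and 0 of 19 mitosis genes passed, and adjusted over the list alone 0 passed as well. At an unadjusted p under 0.05 there were 8, 5 and 2 of them. Their medians were 0.22, 0.09 and -0.03 (camera adjusted p = 0.125, 0.168 and 0.744), and the stress list reached 0.0341 without unstimulated array 2. The stress median was 0.13 and 0.34 without stimulated arrays 1 and 2. Without unstimulated array 1 the replication and mitosis medians were 0.23 and 0.13, without unstimulated array 2 they were 0.06 and -0.25, without stimulated array 1 0.10 and 0.03, and without stimulated array 2 0.18 and -0.09. The largest change in each of these lists was 0.81 ± 0.18 for the chaperone CALR (SE; adjusted p = 0.0536), 0.65 for CDC45 and 0.62 for BUB1. CALR passed with the 50th percentile filter (0.0492), a pseudocount of 16 (0.0385) and an intensity trend in the prior variance (0.0447).

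No list of markers of other cell types that a tonsil sort or culture could hold passed camera with all 4 arrays. Of 9 T cell markers, UBASH3A, a regulator of T cell receptor signalling, fell by 2.11 and 8 did not pass (adjusted over the list alone, 1 fell; median -0.51, camera adjusted p = 0.0538). The T cell list was past the threshold and lower with no filter (0.0326), the mean of probe sets (0.0475) and centring (0.0374), and without unstimulated array 1 (median -0.85, adjusted p = 0.00129) or stimulated array 2 (-0.96, 0.00279). Its median was -0.0047 without unstimulated array 2 (adjusted p = 0.374), -0.08 without stimulated array 1 (0.299) and -0.25 with no filter. Of 8 natural killer cell markers, the adaptor gene SH2D1B fell by 1.71 and 7 did not pass (adjusted over the list alone, 1 rose and 1 fell), and the list's median of -0.01 and mean of 0.07 differed in sign, with a downward camera direction (adjusted p = 0.744). Without unstimulated arrays 1 and 2 this median was -0.15 and 0.08, and without stimulated arrays 1 and 2 it was -0.04 and 0.07. SH2D1B missed the threshold without either stimulated array (up to 0.0525). Of 6 measured monocyte, macrophage and dendritic cell markers, the proteoglycan gene VCAN and the lysosomal gene CD68 rose and 4 did not pass (adjusted over the list alone, 2 rose). VCAN and CD68 missed the threshold without stimulated array 1 (0.0588 and 0.0642). The median of this list was -0.02 while its mean of 0.83 and its camera direction were upward (adjusted p = 0.236), and the median was 0.15 without stimulated array 1. By limma, 0 of 8 B and plasma cell markers passed (0 at an unadjusted p under 0.05; adjusted over the list alone, 0; camera adjusted p = 0.296). Likewise 0 of 8 stromal, endothelial and epithelial markers passed (2 at an unadjusted p under 0.05; adjusted over the list alone, 1 fell; camera adjusted p = 0.130). Too few members for a set test were measured of the type 2 cytokine list (3, of which IL13, chosen after its values were seen, rose), the mast cell list (2, of which 0 passed) and the erythroid and platelet list (2, of which 0 passed).

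Of 13 genes often used as references, TFRC (1.81) and HPRT1 (1.06) rose and 11 did not pass (adjusted over the list alone, 4 rose). TFRC is the transferrin receptor and HPRT1 a purine salvage enzyme. TFRC missed the threshold without unstimulated array 1 or stimulated array 1 (up to 0.0995) and with quantile normalization (0.0633), and HPRT1 passed only without unstimulated array 1 among the 4 omissions (otherwise up to 0.156). This list's median was 0.21 (camera adjusted p = 0.0167; adjusted p = 0.398 with an estimated correlation). It missed the threshold without unstimulated array 1 (0.109) or stimulated array 2 (0.0609), with the 50th percentile filter (0.0584) and with quantile normalization (0.0692).

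Over the 33 lists tested, camera placed 16 higher and 1 lower. With the correlation estimated for each list, 0 of these 17 passed, and 4 lists had an unadjusted p under 0.05. This run rests on the 2 degrees of freedom within groups, so p rises even where the estimated correlation is below the preset. For ribosome biogenesis, at -0.017, the unadjusted camera p went from 1.5e-13 to 0.015. The loss of calls therefore cannot tell whether correlation between genes accounts for the list results. By fry, which asks whether the genes of a list move on balance in 1 direction, 6 lists passed, all of them higher. These were the ILC3 cytokines (adjusted p = 0.0412), the type 1 and cytotoxic genes (0.0485), the NF-kB response (0.0402), and polyamine and nucleotide synthesis, ribosome biogenesis and regulators of apoptosis (0.0328 each).

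**Figure D3:**
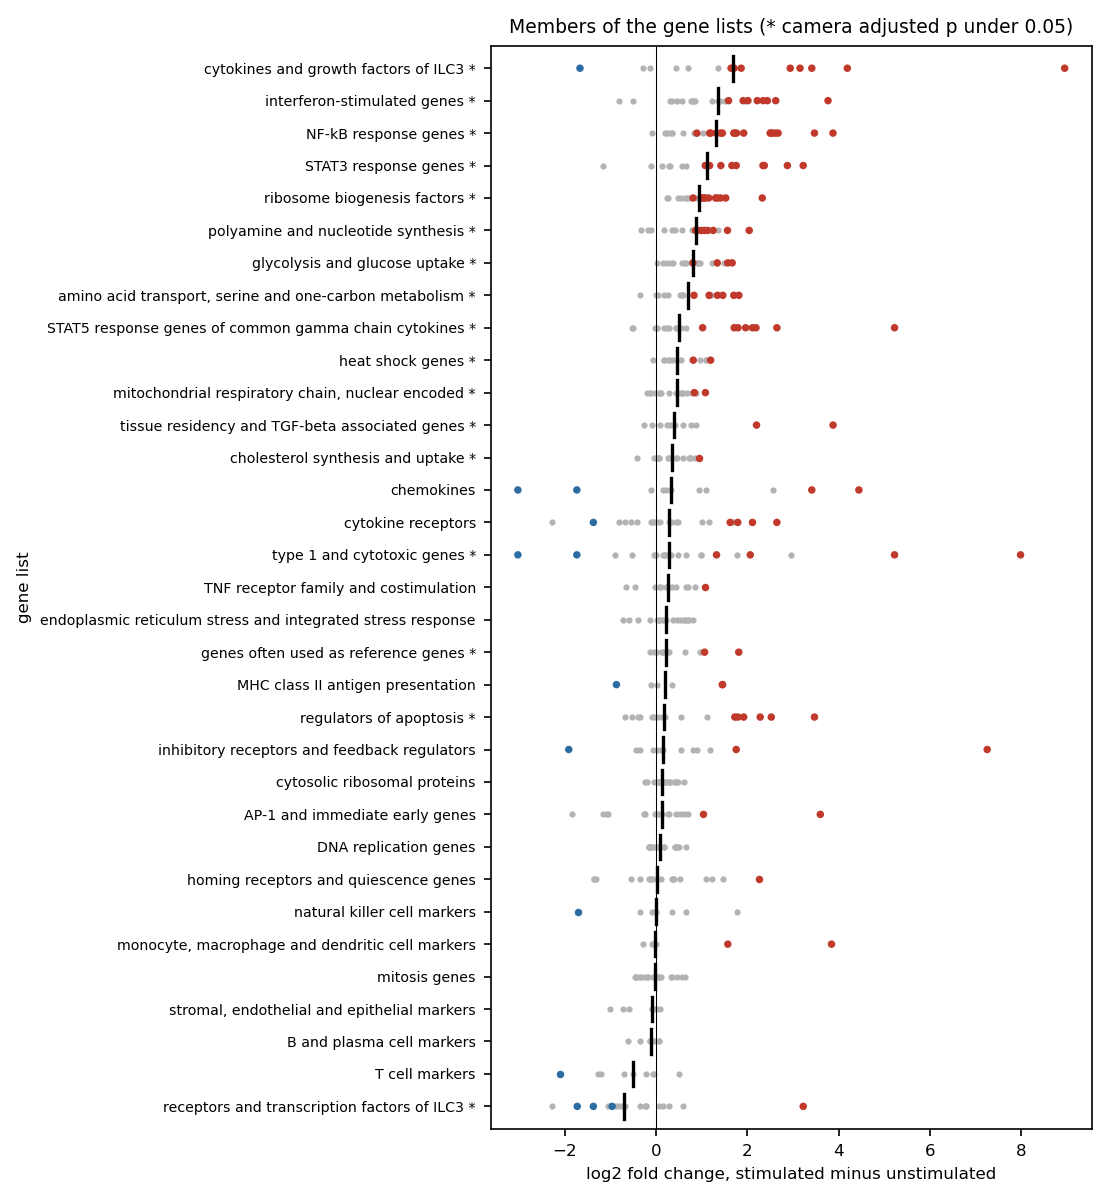
Log2 fold change (stimulated minus unstimulated) of every measured member of the 33 gene lists tested, 1 list per line in order of its median, which is drawn as a black bar. Red points are members that rose, blue points members that fell and grey points the rest, and a star marks the 17 lists with a camera adjusted p under 0.05; the ILC3 cytokines have the highest median at 1.68 and the ILC3 receptors and transcription factors the lowest at -0.70.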

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

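The alternatives were chosen before the data were examined, and all of those listed were run. Apart from the omission of arrays, the directions of all named genes and the camera directions of the fixed lists were kept, with the exception of a pair of lists that did not pass. With the 50th percentile filter the AP-1 list had a median of 0.043 and a downward camera direction (adjusted p = 0.871), and with the replicate number as a block the natural killer marker list had a median of -0.011 and an upward camera direction (adjusted p = 0.766); the causes were not tested. Medians near 0 changed sign without a change of camera direction for homing and DNA replication with quantile normalization, for mitosis and natural killer markers with centring, and for monocyte, macrophage and dendritic cell markers with either. The 764 genes kept their direction in each setting in which they were measured, which was certain in advance for the omissions. Between 610 genes (quantile normalization) and 756 genes (pseudocount of 16) passed under the other filters, scalings, probe rules, pseudocount and prior. The share of calls that were higher was 67.4%, against 59.8% with quantile normalization and 72.6% with centring. With the replicate number as a block, 1282 genes were higher and 859 lower, including the 764, and 2 lists were lower, the T cell markers among them (adjusted p = 0.00239). The 10 named genes that passed with the block but not without it were IL7R (adjusted p = 8.52e-05), IL23R, IL1R1, NCR2, EOMES, CALR, CDC45, BUB1, MANF and PECAM1 (adjusted p up to 0.0499). Deviations of same-numbered arrays correlated at 0.411 across genes, but with 2 pairs and no label that ties a number to a donor the pairing is not established. Besides the ILC3 identity list, the T cell marker list was lower, making 2 lists lower, with no filter, with the mean of probe sets and with centring. Camera with estimated correlation gave 0 lists higher and 0 lower, and fry gave 6 higher and 0 lower. With each array left out in turn, the genes past the threshold ranged from 119 to 457 higher and from 40 to 255 lower, named genes past it from 51 to 85 against 94 with all arrays, lists higher from 14 to 21 and lists lower from 1 to 2. An omission leaves 1 array in a group and fewer degrees of freedom. Log2 fold changes that crossed 0 in these omissions ranged from -0.18 to 1.41 for RPL18, -0.10 to 1.08 for RPS19, -1.38 to 0.16 for BANK1, -0.84 to 0.58 for TNF and -0.18 to 0.0021 for NCAM1. List medians ranged from -0.20 to 0.37 for AP-1 and immediate early genes, -0.22 to 0.49 for homing and quiescence, -0.25 to 0.13 for mitosis, -0.15 to 0.080 for natural killer markers, -0.11 to 0.51 for MHC class II presentation and -0.10 to 0.15 for monocyte, macrophage and dendritic cell markers, and none of these genes or lists passed with all arrays. Signal over background could not be assessed without detection calls, which limits what can be said of genes near the low end of the scale, such as IL17A.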

Other observations

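Except for ribosome biogenesis and ribosomal proteins, the gene groups in this part were chosen after the results had been seen. They came from 13 further lists, of which 9 were tested with camera, and camera adjusted p values are over those 9. Those 9 lists were not run under the other filters, scalings or omissions of arrays. All comparisons in this part were also chosen after the results had been seen.

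Beyond ribosome biogenesis, several lists of genes for making, folding and degrading proteins had members that rose. Of 31 subunits of the constitutive proteasome, 12 rose and 0 fell, with a median log2 fold change of 0.85 (camera adjusted p = 8.41e-16; adjusted p = 0.139 with an estimated correlation); PSMB3 rose by 1.48 and PSMA6 by 1.37. Of 14 genes of class I antigen processing, 6 rose and 0 fell, among them the peptide transporter genes TAP2 at 2.47 and TAP1 at 1.80 and the immunoproteasome gene PSMB9 at 1.59 (median 1.09, adjusted p = 3.25e-07; adjusted p = 0.139 with an estimated correlation). Of 20 cytosolic tRNA synthetases, 7 rose (median 0.84, adjusted p = 8.22e-09), and of 8 subunits of the chaperonin CCT, 3 rose (median 0.82, adjusted p = 2.4e-05); both had an adjusted p = 0.139 with an estimated correlation. Among tRNA synthetases WARS1 stood apart at 4.28, with the next highest, MARS1, at 1.31. TAP1, TAP2, PSMB9, PSMB10 and WARS1 also belong to the list of genes favoured by interferon gamma used below, so these lists are not separate observations. With an estimated correlation 2 of the 9 lists had an unadjusted p under 0.05.

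The SLAM family of lymphocyte receptors moved in opposite directions. SLAMF7 and SLAMF1 rose by 4.97 and 2.49, while LY9, SLAMF6, CD244 and the adaptor SH2D1B fell, with log2 fold changes of -1.90, -1.78, -1.38 and -1.71, so that as a list the 8 measured members did not pass (camera adjusted p = 0.0812). Of 8 metallothioneins, which bind zinc and copper, 3 rose, with MT2A at 3.04 (median 0.73, adjusted p = 1.23e-05; adjusted p = 0.139 with an estimated correlation). These genes are similar in sequence, and their probe sets may not tell them apart, which was not tested. Like the other lists tested in this part, the metallothionein list was not run under the other scalings. CYP1A1, a target of the aryl hydrocarbon receptor, fell by 1.93 (adjusted p = 0.00517), while AHR itself did not pass (0.16, and 0.01 to 0.30 with an array left out) and the 8 target genes did not pass as a list (camera adjusted p = 0.0812).

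Several genes better known from myeloid cells rose in these sorted lymphocytes. SERPINA1, IFI30, IRF8, VCAN, CD68, CTSS and CD74, 7 genes in all, had a median log2 fold change of 3.85. Monocytes or macrophages in the stimulated cultures would bring their abundant transcripts. However, 10 of these, among them LYZ, S100A8, S100A9 and CD14, had a median change of -0.021. Their SD between genes was 0.11 and their highest stimulated level was 5.44. Only 2 of the 10 were bright enough to test, and 0 passed by limma (0 at an unadjusted p under 0.05). These transcripts were not chosen to report dendritic cells, which were not addressed. A response of the cultured cells to the interferon gamma that they express was the other explanation weighed, and it stays open. Of 23 measured genes favoured by interferon gamma 18 rose, and of 18 favoured by type I interferon 3 rose (camera adjusted p = 2.99e-20 and 1.11e-06; adjusted p = 0.140 and 0.213 with an estimated correlation). With dim genes included, genes favoured by interferon gamma had a median of 1.80 and genes favoured by type I interferon one of 0.82, a difference of 0.98 (24 and 20 genes). The interferon gamma list holds 4 of the 7 genes to be explained (IFI30, IRF8, CTSS and CD74). IFI30 and IRF8 lie above its median and CTSS and CD74 below it, so without them the difference was bound to stay at 0.98 (20 and 20 genes). Without those and all genes chosen for naming the difference was 0.70 (16 and 19 genes). The lists were assembled with the values known, so this difference decides nothing, and no culture with interferon gamma blocked was analysed here, so direct effects of the added cytokines cannot be told apart from it.

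The rise of IFNG, GZMB, NKG7 and TBX21 might reflect a larger share of natural killer or T cells, although the sort required NKp44 and CD196. Of 16 abundant natural killer and T cell transcripts, 12 were tested, of which 3 fell and 0 rose by limma (5 at an unadjusted p under 0.05), and the median change of the 16 was -0.032. The 3 that fell, XCL1, XCL2 and SH2D1B, were known to fall when the list was assembled. The SD of the 16 between genes was 1.26. GNLY at 1.77 and KLRD1 at 1.43 changed by more than the 1.32 of TBX21. The first did not pass the threshold and the second was too dim to test. None of the 16 rose by as much as NKG7 (2.06), GZMB (5.23) or IFNG (7.99). Between arrays of a group, TRAT1 (SD 2.05 unstimulated, 1.98 stimulated) and GNLY (1.82 and 1.53) varied widely and KLRC1 (0.02 and 0.38) less. These values cannot decide whether a larger share of such cells contributed, or in which cells of the cultures the transcripts were induced. A surface stain or single-cell measurement after the culture would bear on this directly.

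The rise of the growth lists could also stem from scaling between arrays or from a general rise of abundant transcripts. With quantile normalization the median of the ribosome biogenesis list was 0.86 (SD 0.48 between genes), against -0.01 over all genes. With centring these medians were 0.99 and 0.05. Log2 medians of the arrays lay between 5.42 and 5.51 beforehand, so centring could move the list only slightly. RMA had already normalized the values by quantiles, so repeating it cannot show an effect of that step. The deposited arrays still differed slightly in spread, with SDs of log2 values of 1.88 and 1.86 unstimulated and 1.92 and 1.93 stimulated. Repeating quantile normalization lowered the list's median from 0.95 to 0.86, and 610 instead of 764 genes passed the limma threshold. Scaling thus affected the calls of some genes. The list stayed higher under both settings, but this cannot decide whether normalization within RMA contributed to its rise. The ribosomal proteins, the most abundant list, had a median of 0.13 with an SD of 0.22 against 0.95 for ribosome biogenesis. Normalization by quantiles within RMA would largely remove a general rise of abundant transcripts, so this difference cannot decide whether there was one. No biological explanation was tested, and neither were differences in amplification kit between arrays.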
